A study of Mus musculus with 2 samples.

How the data were processed

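The data are 2 Drop-seq libraries of mouse intestinal fibroblast and crypt co-cultures, 1 per condition, each from a pool of 6 cultures released with trypsin and EDTA. The deposited values are whole-number counts per gene and cell barcode without normalization. That they count molecules (UMIs) follows from the Drop-seq protocol named in the labels and is not stated in the files. The submitters' processing notes name STAR 2.6 and build mm10. The counting tool, the annotation and the rule for choosing barcodes are not given in the sources used here. Some barcodes (96 in Ptger4-ON, 152 in Ptger4-OFF) end in N, as deposited. The deposited totals were 7408303 counts in 908 barcodes (Ptger4-ON) and 9490205 counts in 1599 barcodes (Ptger4-OFF).

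Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept, 882 and 1564. Scrublet, run per library in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), called 6 and 4 doublets, which were removed. Counts set to 10000 UMIs per cell, log-transformed and scaled per gene, were clustered jointly with the Leiden method (igraph 0.11.9) at resolution 0.5, from 30 principal components of 2000 variable genes and 15 neighbours. Each cluster was named epithelial-like or fibroblast-like from fixed marker lists. Barcodes that carried both sets of markers (7 and 13), barcodes over 50000 UMIs and pairs of barcodes 1 base apart were kept in the main values and left out as alternatives.

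UMIs were summed per gene over each class of each library and divided by the class total (CPM, counts in each 1000000 UMIs). Class totals were 5533875 and 7603583 UMIs for epithelial-like and 1756918 and 1839148 for fibroblast-like cells. The ratio OFF/ON has an exact conditional binomial 95% interval and each CPM an exact Poisson interval. On the log2 scale, 0.5 was added to each count. A gene needed 20 UMIs over both libraries in the class, which left 11613 genes in epithelial-like and 9757 in fibroblast-like cells. A ratio against a count of 0 is printed with the words at least and computed with 3 counts over the class. It leaves out the counting error of the other library and is not an interval limit. With 1 library per condition, no p-values, standard errors or counts of changed genes were made.

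For gene lists, the median log2(OFF/ON) of measured members was compared with 10000 random lists of the same size drawn from 20 bins of expression, as a description of these libraries, and its interval comes from 1000 Poisson draws of the counts. Lists with under 5 measured members have values only. The 41 lists were fixed before the data were examined and cover markers of epithelial, fibroblast, smooth muscle, pericyte, endothelial, leukocyte, enteric glial, mesothelial, interstitial (Cajal) and erythroid cells, epithelial lineages and states, pathways, stromal gene groups and RNA quality. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs (530 and 1153 epithelial-like, 259 and 348 fibroblast-like cells reached it), with exact Clopper-Pearson intervals. The counts of cells with at least 5 thinned UMIs of a list were added after the data were seen. Intervals cover counting error only.

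Named genes followed a rule written before the data were examined. Among genes with a proper symbol, at least 20 UMIs and at least 100 CPM in either library, and at least 0.5 of the CPM of the other class in the library where they are higher, the 12 largest and 12 smallest ratios of each class were named. To these were added up to 4 members of each list with the largest ratios in either direction, the genes fixed for shares, and the prostaglandin list. Some genes chosen by these rules are not printed or drawn. The rule took its genes from 2216 eligible genes in epithelial-like and 1886 in fibroblast-like cells. Coordinates and transcript lengths come from GENCODE vM21, which held 17154 of the 18309 symbols and 267 of the 268 named genes.

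The ratio and list steps were tested on simulated counts with 200 altered genes, before doublet removal (11642 and 9764 genes). These counts were Poisson draws of class sums, as the intervals assume, without variation between cells or genes that vary together. They check the computation only. Intervals held the true ratio for 95.5% and 95.6% of unaltered genes, and 94.5% and 96% of 200 lists without a difference fell in the middle 95% of random lists. Alternatives were other filters (200 or 500 genes, 10% or no mitochondrial limit, doublets kept), other classes (resolution 1, libraries clustered separately, marker UMIs alone), TMM factors (edgeR 4.0.16, R 4.3.3) and median-of-ratios factors, equal weight for each cell, 10 or 50 UMIs per gene, a pseudocount of 1, members higher in the other class left out, and thinning to 500 UMIs or none. Added after the data were seen were values without the lesser barcode of each pair, without barcodes over 50000 UMIs, without mixed cells, and inside 1 cluster of each class. Figures were drawn with matplotlib 3.10.9.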

Results

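Gene expression was measured by Drop-seq, a droplet method that tags the mRNA of single cells, in co-cultures of mouse intestinal fibroblasts and crypts, the glands that hold the stem cells of the gut lining. The cells came from the small intestine of C57BL6 mice aged 10 weeks. Ptger4 encodes EP4, a receptor for prostaglandin E2. In the Ptger4-ON condition the cultures received DMSO vehicle and grew as spheroids, per the labels. In the Ptger4-OFF condition they received the EP4 antagonist ONO-AE3-208 at 10 µM on alternate days and grew as budding organoids. Each condition had 1 library, made from a pool of 6 cultures, so no value has a replicate error and no test between conditions was possible. Intervals are 95% intervals of counting error only, and do not cover the variation between cells, cultures or mice. Where intervals of both libraries overlap, this alone does not show that a difference lies within counting error.

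The Ptger4-ON library held 908 barcodes and 7408303 unique molecular identifiers (UMIs, which count mRNA molecules), with a median of 4366 per barcode. The Ptger4-OFF library held 1599 barcodes and 9490205 UMIs, with a median of 4161. After filters and removal of called doublets, 876 and 1560 cells remained. In Ptger4-ON, 16 barcodes with over 50000 UMIs held 17.1% of all UMIs, against 6 barcodes and 3.98% in Ptger4-OFF. All of these deep barcodes were epithelial-like, where they held 22.9% and 4.97% of the UMIs of the class.

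The first comparison asked which cells each condition held. Cells fell into epithelial-like clusters, with keratins and Epcam, and fibroblast-like clusters, with collagens. The epithelial-like share was 67.1% [63.9 to 70.2] in Ptger4-ON (588 of 876 cells) and 76.9% [74.8 to 79.0] in Ptger4-OFF (1200 of 1560 cells), with exact Clopper-Pearson intervals. The fibroblast-like cells numbered 288 and 360. Trypsin release can differ between spheroids, buds and fibroblasts, so these shares describe the cells captured. Epithelial markers in fibroblast-like cells reached 1.17% and 1.92% of their level in epithelial-like cells, and fibroblast markers in epithelial-like cells reached 0.281% and 0.319%, which gives the level of free RNA and mixed barcodes.

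Among the epithelial-like cells, a cluster led by Clu, Msln and Ly6a held 182 Ptger4-ON and 74 Ptger4-OFF cells. A cycling cluster led by Top2a and Cenpf held 162 and 369. A cluster led by Nrn1, Ttr and Aqp4 held 148 and 553. A cluster led by the Paneth and goblet genes Defa17, Spink4 and Lyz1 held 70 and 72, a cluster of enterocyte genes (Fabp1, Apoa1, Sis) held 25 and 115, and an enteroendocrine cluster (Chgb, Gip, Cck) held 1 and 17. Fibroblast-like cells formed a larger cluster led by Mgp and Spp1 (237 and 308 cells) and a smaller one led by Grem1 and Mmp10 (51 and 52). Markers of leukocytes summed to 1.99 and 0.658 CPM (counts in each 1000000 UMIs of the class) in epithelial-like cells and to 1.14 and 0.544 CPM in fibroblast-like cells. Erythroid markers had 0 CPM in both classes. Endothelial markers stayed at or under 9.11 CPM and enteric glial markers at or under 3.42 CPM in each class and library. Smooth muscle markers summed to 253 and 267 CPM in fibroblast-like cells, mainly Actg2 (207 and 211 CPM), and pericyte markers to 29.6 and 7.07 CPM. The mesothelial list summed to 450.5 and 114 CPM in epithelial-like cells, nearly all from Msln, and the list for interstitial cells of Cajal to 97.8 and 32.7 CPM, nearly all from Ano1 (95.4 and 31.04 CPM). Msln is also on the fetal-like list.

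The second comparison asked how the crypt-derived epithelium differed when EP4 was blocked. With the antagonist, epithelial-like cells had higher mRNA levels of the absorptive and lipid-handling genes of enterocytes and of enteroendocrine hormones. They had lower levels of the fetal-like and regenerative program and of Paneth and goblet cell genes. Apoa4, an apolipoprotein of chylomicrons, was 13.7-fold (interval 11.8 to 15.9) higher in Ptger4-OFF (33.97 and 464 CPM), and Reg4, a secretory-lineage lectin, was 7.98-fold (interval 6.89 to 9.29) higher in Ptger4-ON (219 and 27.5 CPM). CPM values are given in the order Ptger4-ON, Ptger4-OFF throughout. The crypt stem cell list (median log2 0.14) and the G1/S and G2/M lists (0.06 and 0.02) lay near 0 over the whole class, with differences inside clusters in both directions.

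The enterocyte list had 20 of 22 measured members higher in Ptger4-OFF, with a median log2(OFF/ON) of 0.77 (interval 0.72 to 0.95). This lay above all 10000 random lists matched on expression. Besides Apoa4, these included Lct, the lactase gene, at 3 and 151 UMIs (36.6-fold (interval 12.3 to 179.6) higher), Apoc3 (3.79 and 48.4 CPM), the xenobiotic enzyme Cyp3a11 (7.41 and 89.6 CPM) and Apoa1 (454 and 923 CPM). The list of lipid absorption genes and targets of PPAR, a nuclear receptor for fatty acids, had 18 of 20 members higher (median 0.69 (interval 0.64 to 0.78)). Besides Apoa4, its members included the fatty acid binding protein gene Fabp1 (4.93-fold (interval 4.699 to 5.18) higher, 343 and 1693 CPM) and the thioesterase gene Acot1 (3.05-fold (interval 2.61 to 3.58), 35.8 and 109 CPM). Among the 12 genes with the largest ratios were also the carboxylesterases Ces2a (5.82-fold) and Ces2e (3.56-fold), the deacetylase Aadac (3.90-fold), the cytochrome P450 Cyp2c55 (3.698-fold), Ctrb1, a chymotrypsinogen gene (12.9-fold, 16.8 and 217 CPM), the lipid droplet enzyme Hsd17b13 (4.66-fold), the glutathione transferase Gstm3 (4.78-fold), Apoc2 (4.03-fold) and Chgb (3.895-fold). Without the barcodes over 50000 UMIs, the enterocyte median was 1.29. Inside the enterocyte cluster, which held 4.25% and 9.58% of epithelial-like cells, the list lay the other way, at -0.41, and it had -0.18 in the Paneth and goblet cluster, 1.66 in the cluster led by Clu, 0.43 in the cycling cluster and 0.38 in the cluster led by Nrn1.

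The fetal-like and regenerative list had all 28 measured members lower in Ptger4-OFF (median -1.36 (interval -1.41 to -1.24)), below all 10000 random lists. Ly6a, the gene of the surface marker Sca-1 of regenerating epithelium, had 634 and 195 CPM, and Clu, a marker of revival stem cells, had 1272 and 487 CPM. Anxa1, an annexin of wound healing, was 4.34-fold (interval 4.03 to 4.67) higher in Ptger4-ON, S100a6 3.297-fold, Msln 4.13-fold, Anxa3 3.26-fold, the cornified envelope gene Sprr1a 3.28-fold and the interleukin-1 antagonist gene Il1rn 3.28-fold. The alarmin gene Il33 had 42.3 and 1.58 CPM, Ly6c1 29.8 and 2.37 CPM and Basp1 11.7 and 1.71 CPM. Inside clusters the list's median was -0.02 (led by Clu), -0.81 (cycling), -0.78 (led by Nrn1), -0.91 (Paneth and goblet) and -0.76 (enterocyte). In fibroblast-like cells, which also carry 20 of its members, the median was 0.13, within the range of random lists.

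Goblet cell genes were lower for 12 of 13 measured members (median -1.43 (interval -1.61 to -1.31)). Muc2, the main gel-forming mucin, had 103 and 28.3 CPM, Tff3 had 2841 and 1144 CPM, the lectin gene Zg16 was 6.81-fold (interval 6.07 to 7.64) higher in Ptger4-ON, Ramp1 6.903-fold and the lineage factor Spdef 3.31-fold. Of the Paneth cell genes, 9 of 11 were lower (median -1.46 (interval -1.56 to -1.43)). Lyz1, the lysozyme of Paneth granules, had 376 and 119 CPM, the alpha-defensin genes Defa21 and Defa22 had 22.6 and 2.24 CPM and 25.7 and 4.34 CPM, and Defa3 had 53 and 3 UMIs (24.3-fold (interval 7.87 to 121) higher in Ptger4-ON). Mptx2 went the other way, at 2 and 61 UMIs (22.2-fold (interval 5.89 to 187) higher in Ptger4-OFF). The alpha-defensin genes are close in sequence, so values per gene depend on how reads were assigned. Inside the Paneth and goblet cluster, the medians were -0.70 for Paneth and -0.65 for goblet genes, and inside the cycling cluster 0.09 and -0.16. Inside the cluster led by Nrn1 both lay the other way, at 0.55 and 1.40, and goblet genes had 0.12 in the cluster led by Clu and -4.50 (interval -5.02 to -3.93) in the enterocyte cluster. Values inside the enterocyte cluster rest on 25 Ptger4-ON and 115 Ptger4-OFF cells, here and below. After thinning each cell to 1000 UMIs, 17.2% [14.1 to 20.7] of Ptger4-ON and 6.76% [5.38 to 8.37] of Ptger4-OFF cells had at least 5 Paneth UMIs, and 21.9% [18.4 to 25.7] and 8.24% [6.72 to 9.98] had at least 5 goblet UMIs.

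Enteroendocrine genes were higher for 12 of 13 measured members (median 1.96 (interval 1.76 to 2.22)). The incretin gene Gip had 0 and 647 UMIs (at least 157-fold higher in Ptger4-OFF, with a floor of 3 counts over the class), Gcg, the proglucagon gene, 2 and 428 UMIs (156-fold (interval 42.9 to 1290.2)), Pyy 3 and 230 UMIs (55.8-fold (interval 18.9 to 273)) and the lineage factor Neurod1 0 and 37 UMIs (at least 8.98-fold). With the genes at 0 counts set to this floor, the median was 1.96. Across the alternatives run, the median of the list lay between 1.66 and 2.69. These values rest on few cells, since 2 of 530 Ptger4-ON cells (0.377% [0.0457 to 1.36]) and 18 of 1153 Ptger4-OFF cells (1.56% [0.928 to 2.46]) carried at least 5 thinned UMIs of the list, and these intervals overlap. Of the tuft cell list, 4 members were measured (median 3.24, or 1.98 with zero counts at 3): Rgs13 (0 and 50 UMIs, at least 12.1-fold) and Lrmp (0 and 31 UMIs, at least 7.52-fold) were higher, Avil (32 and 26 UMIs) was lower, and Hpgds had 6 and 17 UMIs.

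The crypt stem cell list had a median of 0.14 (interval 0.00 to 0.25), with 9 members higher and 6 lower. Inside clusters it was -0.15 (led by Clu), -0.21 (cycling), 0.26 (led by Nrn1), 0.087 (Paneth and goblet) and 1.41 (enterocyte). Lgr5, the receptor that marks crypt base stem cells, had 96.1 and 110.2 CPM, Ascl2 27.8 and 32.9 CPM, Smoc2 121 and 262 CPM, Aqp4 68.3 and 142 CPM, Olfm4 7.05 and 16.6 CPM and the lower member Sox9 205 and 124 CPM. The G1/S list (median 0.06) and the G2/M list (0.02) lay within the range of random lists over the whole class. Inside clusters the G1/S median was -0.55 (cluster led by Clu), 0.055 (cycling), 0.034 (led by Nrn1), 0.46 (Paneth and goblet) and 0.46 (enterocyte), and the G2/M median -0.22, 0.12, -0.10, 0.21 and 1.85 in the same order. The proliferation marker Mki67 had 576 and 583 CPM, Cdc45 19.2 and 26.7 CPM, and the mitotic regulators Tacc3 and Ccnb2 had 107 and 83.3 CPM and 182 and 145 CPM.

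**Figure D1:**
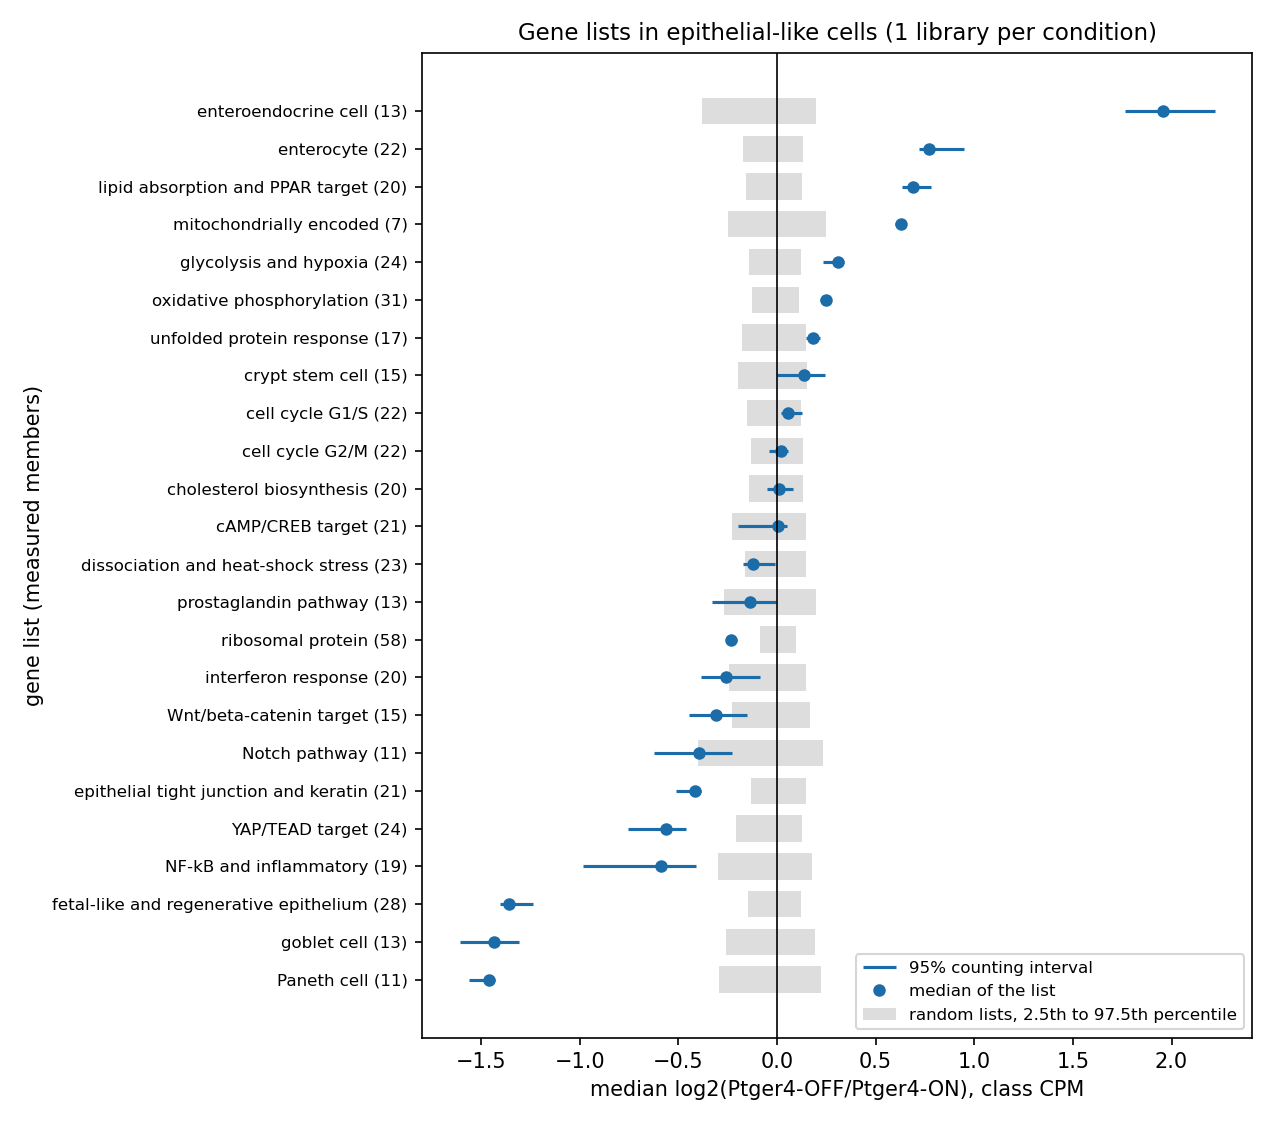
Gene lists in epithelial-like cells. Points give each list's median log2(Ptger4-OFF/Ptger4-ON) with its 95% counting interval, grey bars the middle 95% of 10000 random lists, and numbers in brackets the measured members. Of the lists drawn, those of epithelial genes, pathways and RNA quality with 5 measured members or more, the enteroendocrine list lies highest at 1.96 and the Paneth list lowest at -1.46.

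**Figure D2:**
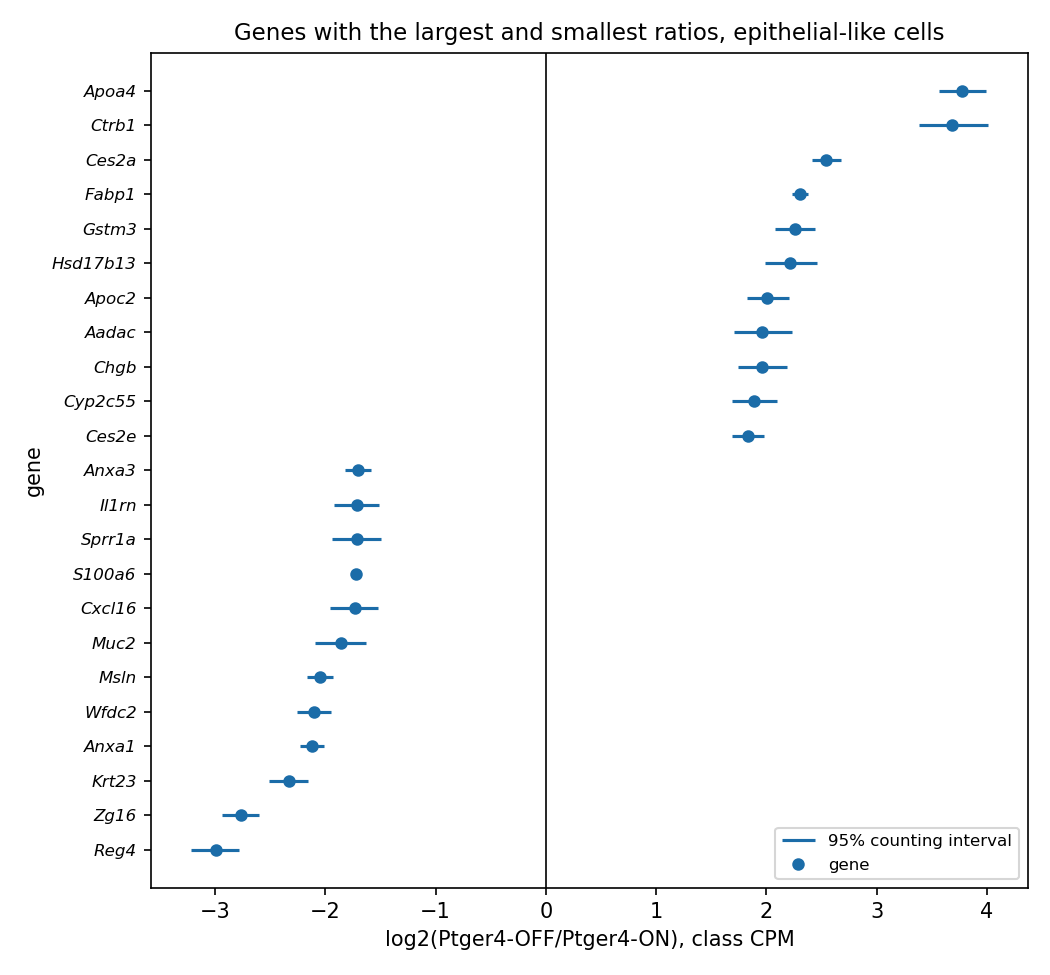
Genes among the 12 largest and the 12 smallest ratios in epithelial-like cells, 1 of which is not shown. Points give log2(Ptger4-OFF/Ptger4-ON) and lines the 95% counting interval, from -2.99 for Reg4 to 3.77 for Apoa4.

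Signalling lists in epithelial-like cells were mostly lower in Ptger4-OFF. Targets of YAP and TEAD, the effectors of the Hippo pathway, had 21 of 24 members lower (median -0.56 (interval -0.75 to -0.46); inside clusters -0.11 led by Clu, -0.17 cycling, -0.24 led by Nrn1, -0.48 Paneth and goblet, -0.03 enterocyte), with Ankrd1 at 53 and 1 UMIs (72.8-fold (interval 12.5 to 2929.9) higher in Ptger4-ON) and Myof at 89.99 and 25.6 CPM. The NF-kB and inflammatory list had 15 of 19 lower (median -0.59 (interval -0.99 to -0.41)), with the chemokine gene Cxcl2 at 9.22 and 2.104 CPM, Tnf at 20.1 and 5.79 CPM and, in the other direction, Tnfaip2 at 2 and 21 UMIs (7.64-fold (interval 1.87 to 67.2)). Tight junction and keratin genes had 19 of 21 lower (median -0.42 (interval -0.51 to -0.38)), among them Krt23 (5.03-fold higher in Ptger4-ON), Cldn4 (2.51-fold), Krt7 (2.21-fold) and F11r (1.87-fold). Inside clusters their median was 0.04 (led by Clu), -0.33 (cycling), -0.41 (led by Nrn1), -0.31 (Paneth and goblet) and -0.83 (enterocyte). The Notch list had a median of -0.39 (interval -0.62 to -0.23), within the range of random lists, with Atoh1 and Jag2 at 12.5 and 3.95 CPM and 8.67 and 3.95 CPM, and the Wnt target list -0.31 (interval -0.44 to -0.15), with Ccnd1 (cyclin D1), Ephb3 and Cd44 at 428 and 204 CPM, 24.4 and 11.97 CPM and 173 and 94.96 CPM. Cxcl16, a chemokine gene, and Wfdc2, a secreted antiprotease gene, were 3.33-fold and 4.28-fold higher in Ptger4-ON. The cAMP and CREB target list, genes driven by the second messenger of EP4, had a median of 0.01 (interval -0.20 to 0.05), with 11 members higher and 10 lower, and 0.50 inside the enterocyte cluster; Gem and Rgs2 had 8.85 and 4.21 CPM and 30.4 and 15.1 CPM, and Pck1 had 5 and 15 UMIs.

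Mitochondrial and several metabolic lists were higher in Ptger4-OFF epithelial-like cells, but not cholesterol synthesis. All 7 measured mitochondrially encoded genes were higher (median 0.63 (interval 0.60 to 0.65)), such as mt-Cytb (3708 and 6094 CPM) and mt-Nd1 (3702 and 6084 CPM); the median mitochondrial share per epithelial-like cell was 2.32% and 3.30%. Nuclear genes of oxidative phosphorylation had 24 of 31 higher (median 0.25 (interval 0.22 to 0.28)), including Uqcrc2 (432 and 617 CPM), with Cox7c lower (272 and 189 CPM). Inside clusters their median was 0.06 (led by Clu), 0.11 (cycling), 0.09 (led by Nrn1), 0.19 (Paneth and goblet) and 0.41 (enterocyte). The glycolysis and hypoxia list had a median of 0.31 (interval 0.24 to 0.34), with 0.18 inside the cluster led by Clu, 0.29 in that led by Nrn1, 0.52 in the enterocyte cluster, -0.02 in the cycling and 0.0040 in the Paneth and goblet cluster. Ndrg1 and Ankrd37 had 223 and 525 CPM and 63.97 and 135 CPM, and Hk1 had 37.04 and 19.7 CPM. The unfolded protein response list had 14 of 17 higher (median 0.18 (interval 0.15 to 0.22)), with Trib3 and Ddit3 at 16.1 and 29.3 CPM and 27.1 and 41.95 CPM. Cholesterol synthesis genes divided evenly over the class (0.01) but had -0.49 inside the enterocyte cluster, with Fdft1 at 96.9 and 73.5 CPM. Ribosomal protein genes were lower for 46 of 58 members (median -0.23 (interval -0.25 to -0.20)), most of all Rpl38 (348 and 139.5 CPM), but the median was 0.24 inside the enterocyte cluster, with 45 of 54 members higher. The dissociation and heat-shock list had a median of -0.12 (interval -0.17 to -0.01), within the range of random lists, with Ier3 and Hspa1b at 171 and 86.1 CPM and 11.2 and 3.81 CPM. Of the MHC class II list 2 members were measured (median 0.93, H2-Ab1 11.2 and 23.9 CPM).

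Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs, since the median depths of epithelial-like cells were 4621 and 4159.5 UMIs, and of fibroblast-like cells 4612.5 and 4473.5. Ly6a UMIs were seen in 23.6% [20.03 to 27.4] of Ptger4-ON and 5.64% [4.38 to 7.13] of Ptger4-OFF cells in the epithelial-like class (2.32% and 2.01% in fibroblast-like cells; unthinned, 41.3% and 10.6%). For Clu the shares were 26.98% [23.2 to 30.98] of Ptger4-ON and 7.55% [6.09 to 9.22] of Ptger4-OFF cells (2.32% and 0.287%; unthinned 48.3% and 16.1%), for Tff3 30.2% [26.3 to 34.3] of Ptger4-ON and 14.7% [12.7 to 16.8] of Ptger4-OFF cells (6.56% and 4.31%; unthinned 45.7% and 26.2%) and for Fabp1 3.02% [1.74 to 4.86] of Ptger4-ON and 12.1% [10.2 to 14.1] of Ptger4-OFF cells (0.386% and 2.299%; unthinned 5.61% and 22.3%). Lgr5 was seen in 6.42% [4.48 to 8.85] of Ptger4-ON and 10.2% [8.54 to 12.1] of Ptger4-OFF cells (0% and 0.575%; unthinned 29.8% and 35.8%), where the intervals overlap, and Mki67 in 32.8% [28.8 to 37.01] of Ptger4-ON and 32.4% [29.7 to 35.1] of Ptger4-OFF cells (1.93% and 3.45%; unthinned 57.8% and 56.6%). Dclk1, a tuft cell gene, was seen in 0.189% [0.00478 to 1.05] of Ptger4-ON and 0.173% [0.02101 to 0.625] of Ptger4-OFF cells against 12.4% and 15.2% of fibroblast-like cells (unthinned 0.5102% and 0.5%).

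**Figure D3:**
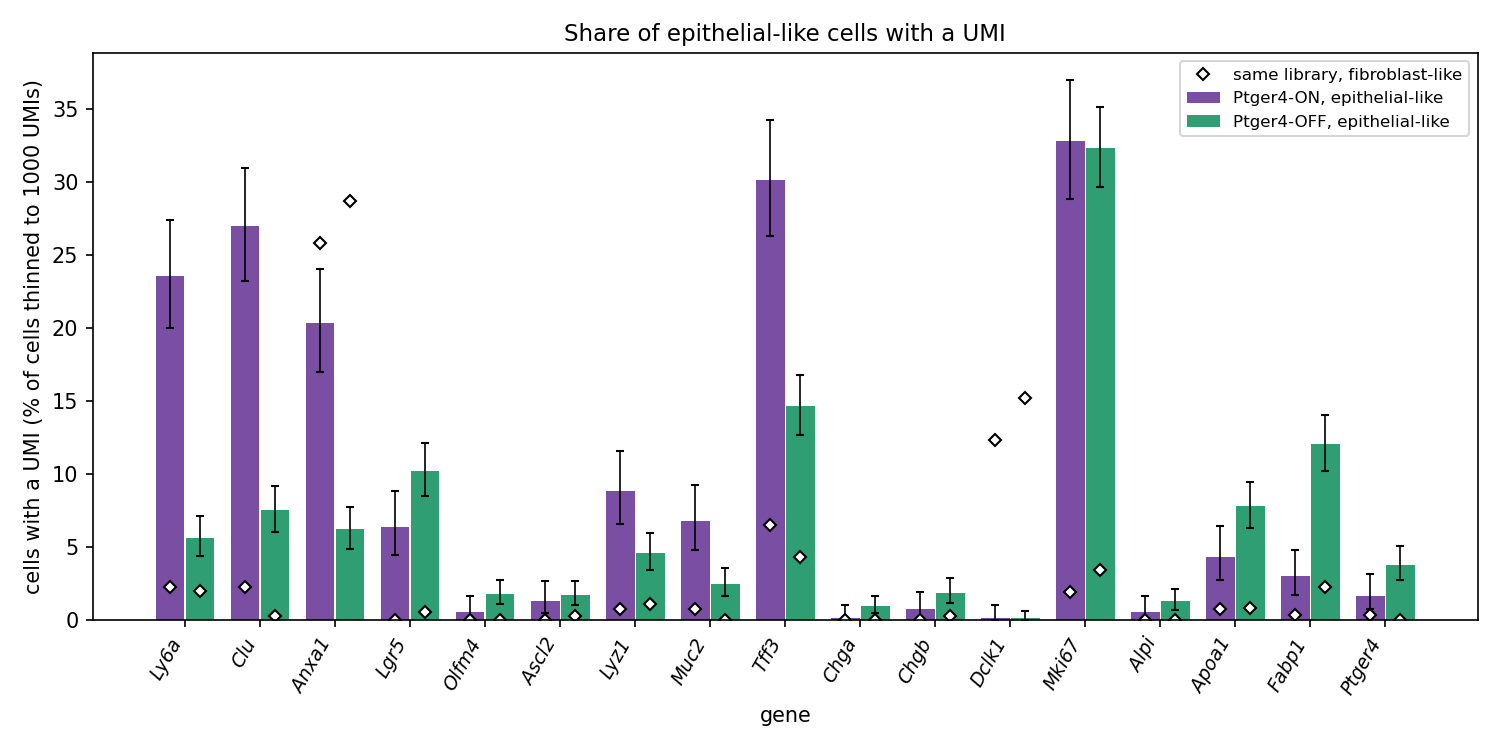
Share of epithelial-like cells with a UMI of fixed genes, 1 of which is not shown, in percent of cells thinned to 1000 UMIs. Bars with exact 95% intervals are the libraries and diamonds the fibroblast-like cells of the same library; Clu reaches 27.0% and 7.55%.

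In genome build mm10 with GENCODE vM21 annotation, all of the following are protein-coding genes. Ptger4 lies on chromosome 15 at 5206661 to 5244187 (ENSMUSG00000039942.15), Ly6a on chromosome 15 at 74994877 to 74998031 (ENSMUSG00000075602.10), Clu on chromosome 14 at 65968483 to 65981547 (ENSMUSG00000022037.15), Apoa4 on chromosome 9 at 46240696 to 46243459 (ENSMUSG00000032080.6) and Fabp1 on chromosome 6 at 71199827 to 71205023 (ENSMUSG00000054422.7). Reg4 lies on chromosome 3 at 98222156 to 98236748, Muc2 on chromosome 7 at 141690340 to 141754693, Lgr5 on chromosome 10 at 115450311 to 115587780, Gip on chromosome 11 at 96024545 to 96030831, Il33 on chromosome 19 at 29925114 to 29960718, Il11 on chromosome 7 at 4772373 to 4782859, Ptgs2 on chromosome 1 at 150100031 to 150108227 and Grem1 on chromosome 2 at 113746164 to 113758646.

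The prostaglandin genes divided between the classes. Ptger4 mRNA was mainly epithelial, at 26.9 and 29.3 CPM (1.09-fold (interval 0.881 to 1.35)) in epithelial-like cells. Fibroblast-like cells had 2 and 1 UMIs (2.09-fold (interval 0.109 to 124) higher in Ptger4-ON). These class sums showed no difference in Ptger4 level beyond counting error. Thinned, Ptger4 was seen in 1.70% [0.779 to 3.20] of Ptger4-ON and 3.82% [2.79 to 5.09] of Ptger4-OFF epithelial-like cells, with overlapping intervals (unthinned 15.8% and 15.6%). Ptgs2, the inducible cyclooxygenase, was mainly in fibroblast-like cells, at 788 and 632 CPM (1.25-fold (interval 1.15 to 1.35) higher in Ptger4-ON), against 13.9 and 1.97 CPM in epithelial-like cells. Thinned, Ptgs2 was seen in 44.02% [37.9 to 50.3] of Ptger4-ON and 35.6% [30.6 to 40.9] of Ptger4-OFF cells in the fibroblast-like class (0.943% and 0.0867% in epithelial-like cells; unthinned 65.6% and 66.4%), with overlapping intervals. The synthase genes Ptges and Ptgis had 77.4 and 81.6 CPM and 82.5 and 121 CPM in fibroblast-like cells, and Ptgs1 58.6 and 49.5 CPM. The list as a whole had medians of -0.14 in epithelial-like and 0.16 in fibroblast-like cells. In epithelial-like cells Cbr1, a carbonyl reductase gene, had 240.0 and 387 CPM, the degrading enzyme Hpgd 28.01 and 34.6 CPM, the exporter Abcc4 22.2 and 9.73 CPM, the transporter Slco2a1 7.05 and 2.76 CPM, Ptges 4.88 and 1.05 CPM, Ptges2 61.6 and 56.03 CPM, Ptges3 249 and 194 CPM, Ptgr1 320.0 and 322 CPM, Akr1b3 36.3 and 28.01 CPM and Pla2g4a 57.1 and 63.4 CPM. In fibroblast-like cells Pla2g4a had 224 and 208 CPM, Ptges2 30.2 and 35.3 CPM, Ptges3 147 and 120.2 CPM, Cbr1 53.5 and 58.2 CPM, Ptgr1 89.9 and 104 CPM, Akr1b3 18.2 and 27.2 CPM, Abcc4 5.69 and 10.3 CPM and Slco2a1 4.55 and 4.35 CPM. The other prostanoid receptors Ptger1, Ptger2, Ptger3, Ptgir and Ptgfr had at most 18 UMIs per class and library, and so did Tbxas1, Ptgds and Hpgds.

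The third comparison asked how the fibroblasts differed, although Ptger4 mRNA was near 0 in them. With the antagonist, fibroblast-like cells had higher levels of interferon-response and cholesterol synthesis genes, and lower levels of single growth factor, cytokine and matrix genes. The chemokine and cytokine list went both ways, with 8 of 15 members higher, among them Il33, 7 lower and a median of 0.01. Over genes with 500 UMIs or more, the SD of log2(OFF/ON) across genes was 0.24 (1372 genes), against 0.41 in the epithelium (4803 genes). This cut reaches lower CPM in the epithelium, which has more UMIs, so the SDs cover unlike genes and are not directly comparable. Il33 was 2.51-fold (interval 2.205 to 2.87) higher in Ptger4-OFF (181 and 455 CPM), and Ctgf, a matricellular growth factor gene and YAP target, was 2.295-fold (interval 1.98 to 2.66) higher in Ptger4-ON (337 and 147 CPM).

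Interferon-response genes were higher for 21 of 22 measured members (median 0.66 (interval 0.51 to 0.86)), above all 10000 random lists. The antiviral genes Ifit1 and Ifit3 had 7.399 and 29.9 CPM and 7.97 and 29.9 CPM, Usp18 5.12 and 16.3 CPM and Rsad2 1 and 23 UMIs (21.97-fold (interval 3.57 to 905) higher). Irgm1, an interferon-inducible GTPase gene, was 2.097-fold higher. In epithelial-like cells the same list had a median of -0.26 (interval -0.38 to -0.08), with Ifitm3 higher (40.5 and 115 CPM). Inside the epithelial-like clusters the median was above 0 in 4 of the 5 with values. It was 0.25 (interval 0.03 to 0.42) in the cluster led by Clu and 0.27 (interval 0.004 to 0.42) in the cluster led by Nrn1. In the cycling cluster (0.23 (interval -0.03 to 0.35)) and the Paneth and goblet cluster (0.11 (interval -0.20 to 0.31)) the interval includes 0. The enterocyte cluster had a lower value in Ptger4-OFF (-0.45 (interval -0.76 to -0.16)). Cholesterol synthesis genes were higher for 19 of 19 members (median 0.46 (interval 0.34 to 0.64)), with Sc5d (1.72-fold (interval 1.37 to 2.17)), Nsdhl (1.88-fold), Pmvk (1.68-fold) and the regulator Insig1 (1.68-fold). Lipid and PPAR target genes had a median of 0.26 (interval 0.11 to 0.43), with Plin2 and Acadm at 85.4 and 121 CPM and 50.1 and 71.2 CPM. Unfolded protein response genes had 0.15 (interval 0.07 to 0.21), within the range of random lists, with Xbp1 and Calr at 100.2 and 132 CPM and 1135 and 1412 CPM. Also among the 12 largest ratios were Cav1, the caveolin gene (1.84-fold), the peroxiredoxin gene Prdx4 (1.72-fold), Eci2 (1.70-fold), Rgs10 (1.66-fold), Ppp1r7 (1.63-fold), Lgals3bp (1.63-fold), Emp3 (1.62-fold), Cth (1.59-fold) and Pon3 (1.58-fold).

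Among the 12 smallest ratios, all higher in Ptger4-ON, were the Wnt antagonist gene Dkk2 (2.21-fold), Inhba, which encodes the activin A subunit (2.08-fold), Tagln, a smooth muscle cytoskeletal gene (2.04-fold), the cytokine gene Lif (1.93-fold), hexokinase 2 (Hk2, 1.95-fold), Pi15 (2.004-fold), Cebpz (1.95-fold), Lars2 (1.92-fold), Cox7c (1.898-fold) and the ribosomal genes Rpl38 (2.25-fold) and Rps28 (1.98-fold). Il11, a cytokine gene, had 59 and 1 UMIs (61.8-fold (interval 10.7 to 2480.3) higher in Ptger4-ON), Il6 59.8 and 29.9 CPM, and Mmp9, a gelatinase gene, 67.7 and 21.2 CPM. The chemokine and cytokine list had a median of 0.01 (interval -0.06 to 0.20) and the NF-kB list -0.17 (interval -0.27 to 0.02), with 12 of 20 members lower and a median below the range of random lists. Inside the smaller and the larger cluster, however, the NF-kB median was 0.04 and 0.06, with intervals that include 0. The chemokine and cytokine median was 0.035 (interval -0.187 to 0.294) inside the smaller cluster and 0.21 (interval 0.08 to 0.305) inside the larger. The niche signal list had a median of -0.07 (interval -0.36 to 0.07). Of its members, the BMP antagonist gene Grem1 had 1779 and 1234 CPM, Fgf7 126 and 79.4 CPM and Rspo3, which sustains crypt stem cells, 145 and 115 CPM. The matrix list had 17 of 27 lower (median -0.15 (interval -0.18 to -0.09)), with Col12a1 (200.4 and 123 CPM), Col4a1 (715 and 461 CPM), Tnc (1293 and 912 CPM) and Col1a1 (2937 and 2094 CPM). The protease list had a median of -0.07 (interval -0.18 to -0.01) (Mmp10 161 and 106 CPM), but 0.18 inside the smaller cluster and -0.14 inside the larger. The contractile list had -0.11 (interval -0.17 to -0.01) (Acta2 414 and 297 CPM, Myl9 169.6 and 229 CPM). The class medians of the protease and contractile lists lay within the range of random lists. The pericyte markers Kcnj8 and Cspg4 had 22 and 4 UMIs and 16 and 5 UMIs. YAP/TEAD targets had -0.16 (interval -0.28 to -0.04), with -0.52 inside the smaller cluster and -0.10 inside the larger. The cAMP and CREB targets had -0.25 (interval -0.28 to -0.01), but 0.28 inside the smaller cluster and -0.09 inside the larger, with Nr4a1 at 27.9 and 10.3 CPM and Crem, in the other direction, at 15.9 and 26.6 CPM.

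**Figure D4:**
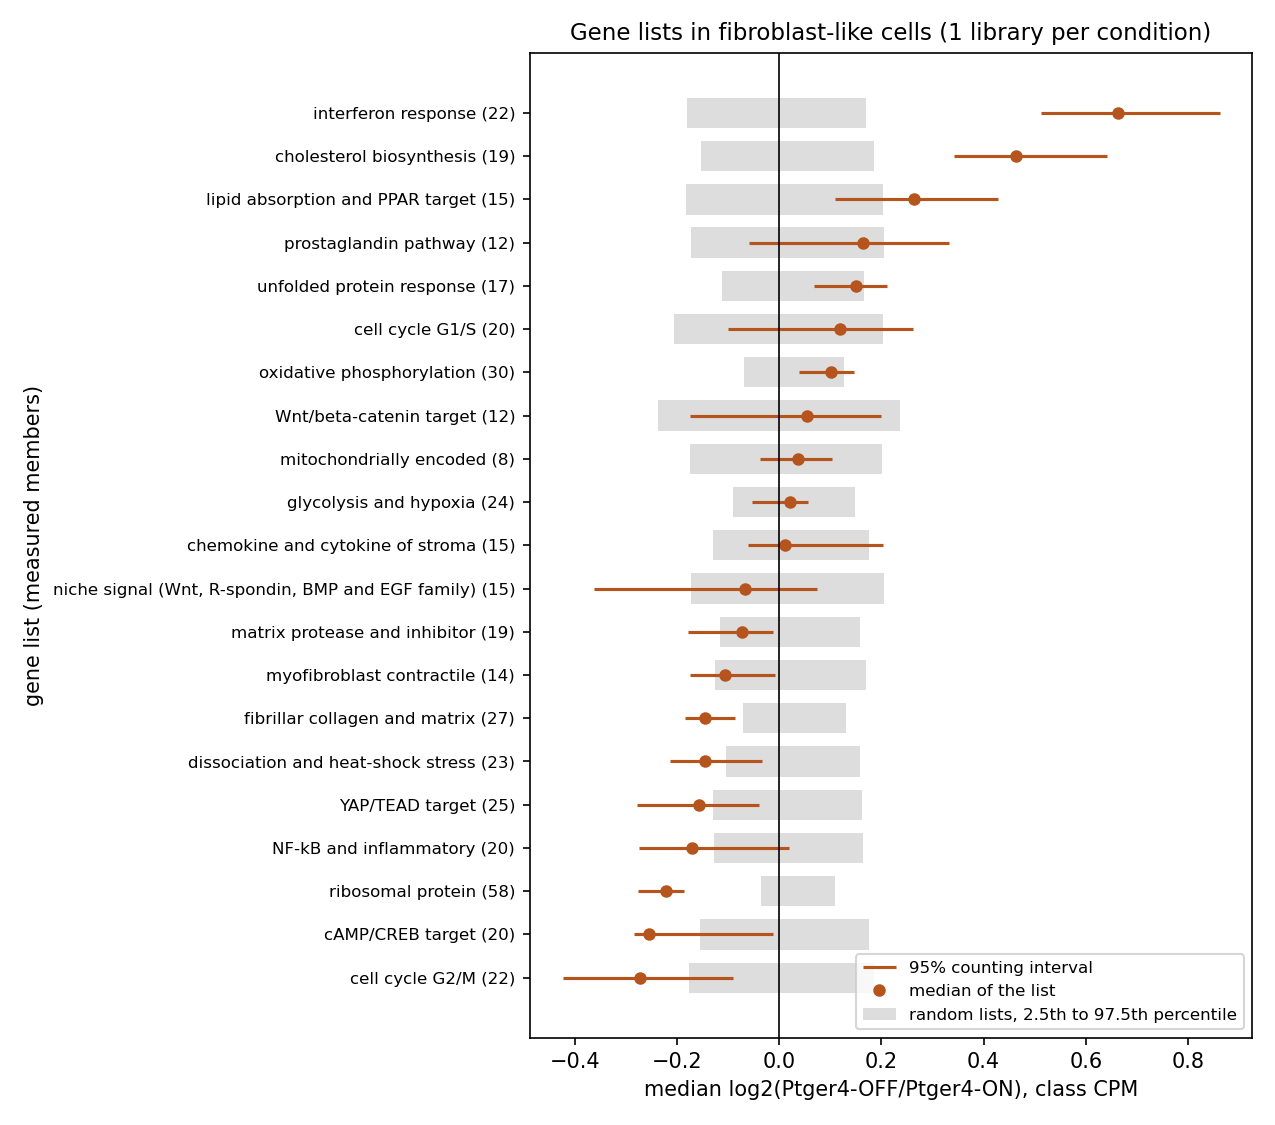
Gene lists in fibroblast-like cells, drawn as for the epithelial-like class: median log2(Ptger4-OFF/Ptger4-ON), 95% counting interval and the middle 95% of random lists (grey). The lists drawn are those of fibroblast gene groups, pathways and RNA quality, and of these the interferon list lies highest at 0.66.

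**Figure D5:**
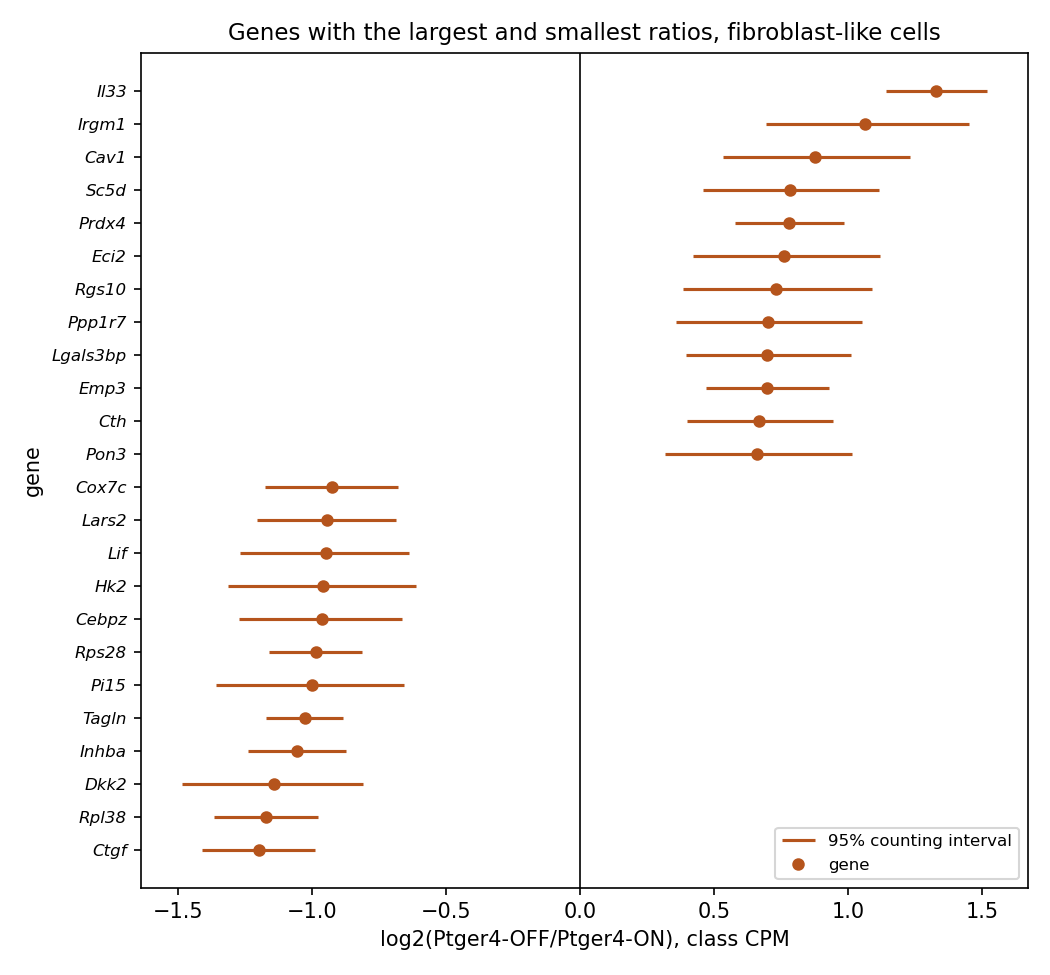
The 12 genes with the largest and the 12 with the smallest ratios in fibroblast-like cells, as log2(Ptger4-OFF/Ptger4-ON) with 95% counting intervals, from -1.20 for Ctgf to 1.33 for Il33.

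The G2/M list had a median of -0.27 (interval -0.42 to -0.09) (Hmmr 68.9 and 33.7 CPM), but 0.05 with each cell weighted equally; the G1/S list had 0.12. Ribosomal protein genes were lower for 47 of 58 members (median -0.22 (interval -0.28 to -0.19)). Oxidative phosphorylation (0.10), glycolysis and hypoxia (0.02), Wnt targets (0.06) and mitochondrially encoded genes (0.04) had medians within the range of random lists. The dissociation and heat-shock list, a sign of handling stress, was lower in Ptger4-OFF (median -0.15 (interval -0.21 to -0.03)), below the range of random lists and about as low as the matrix list. Inside the smaller and the larger cluster the stress median was 0.02 (interval -0.14 to 0.16) and -0.08 (interval -0.21 to -0.001). The matrix list had -0.16 inside both clusters. The Notch list had 2 measured members (median -0.29). In the fibroblast-like class, Ptger4 UMIs were seen in 0.386% [0.00977 to 2.13] of Ptger4-ON and 0% [0 to 1.05] of Ptger4-OFF cells after thinning. For 0 of 348 cells, a limit of 3 cells gives 0.862%, a different rule from the exact interval that ends at 1.05%. Neither limit says anything of cells that express the gene without a UMI. The epithelial-like share after thinning was 1.698% and 3.82%, and the unthinned share in fibroblast-like cells 0.694% and 0.278%.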

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

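Tests chosen only after the result was seen were those of free RNA for the fetal-like and the interferon lists, of short transcripts outside the ribosomal genes, and of deep barcodes for short transcripts. The last replaced a test written before its value was known, which gave -0.145, between its bounds of -0.1 and -0.2, and a second, which asked whether the fibroblast-like class alone had the difference and could not have come out otherwise. The test of free RNA for the interferon list replaced one of the direction in epithelial-like cells, which differs between clusters. The spread of each test, from resampled members or genes, and the rule that it must stay clear of the bound on the other side were also added after the values were seen. Lists and genes are given here because the epithelial-like and fibroblast-like classes lay on opposite sides of 0 beyond counting error. These differences between classes were not tested.

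The fetal-like and regenerative list had a median log2(OFF/ON) of -1.36 in epithelial-like and 0.13 in fibroblast-like cells. The fibroblast-like value lay within the range of random lists. With each cell weighted equally the epithelial median was -1.53 [-1.96 to -0.88], which argues against the deep barcodes of the Ptger4-ON library. Free fibroblast RNA would give 0.0926% [0.00428 to 0.272] of the median member's level in Ptger4-ON epithelial-like cells, although 111% for Spp1. Inside the cycling cluster the median was -0.81 [-1.18 to -0.75], which argues against another mix of epithelial clusters alone, although the cluster led by Clu showed -0.02 and a cluster can hold a range of states. The median was -0.78 in the cluster led by Nrn1, -0.91 in the Paneth and goblet cluster and -0.76 in the enterocyte cluster. That EP4 blockade may have lowered this program is a hypothesis that no test here decides, and a difference between the pools or in their preparation remains open because each condition had 1 library.

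The interferon list had medians of -0.26 in epithelial-like and 0.66 in fibroblast-like cells. However, the epithelial-like median was 0.25, 0.23, 0.27 and 0.11 inside 4 clusters and -0.45 inside the enterocyte cluster. Of these, the counting intervals of 0.23 and 0.11 include 0. Over the 7 members left when those higher in the other class are left out, the epithelial-like median was -0.0587. Without the 5 highest fibroblast-like cells of each library the fibroblast-like median was 0.66 (0.6637 [0.511 to 0.986]), and inside the larger fibroblast-like cluster 0.66 (0.6602 [0.507 to 1.25]), which argues against a few cells and against another mix of clusters. Free RNA from epithelial-like cells would give 0.536% [0.17 to 1.11] of the median member's level in Ptger4-OFF fibroblast-like cells, and 5.14% for H2-K1, the highest of the 22 members, which argues against it. A response of the fibroblasts to the antagonist, direct or through the epithelium, is a candidate explanation, and Ptger4 had 2 and 1 UMIs in them. A difference between pools, such as exposure to a virus or to damaged cells, was not tested and cannot be separated from the treatment.

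Short transcripts (under 600 nt) had lower ratios than other genes in both classes, with differences of medians of -0.0822 (a spread from -0.172 up to 0) in epithelial-like and -0.145 [-0.231 to -0.0817] in fibroblast-like cells. Outside the ribosomal genes the difference was -0.0237 [-0.133 to 0.0718] in epithelial-like and -0.0997 [-0.155 to -0.0556] in fibroblast-like cells. This cannot decide whether short transcripts were lost in 1 library, since the bound set for such a loss exceeded the whole difference in both classes. The fibroblast-like spread lies below 0. Ribosomal protein genes under 600 nt had medians of -0.49 (epithelial-like) and -0.40 (fibroblast-like), against -0.21 in both classes for those of 800 nt or more. Whether deep barcodes gave the epithelial-like difference cannot be told apart, since without them it was -0.0602 [-0.15 to 0.0205], and the fibroblast-like class held 0 cells over 50000 UMIs. With each cell weighted equally, the difference was -0.0281 in epithelial-like and -0.15 in fibroblast-like cells. Outside the ribosomal genes it was then 0.0333 and -0.0786. These equal-weight values have no spread. Whether ribosomal protein genes were lower as a group cannot be told apart from length, since those of 800 nt or more had -0.2122 [-0.371 to -0.0611], a spread that reaches both bounds, and the whole list had 0.24 inside the enterocyte cluster. S6 kinase genes, included by error, were taken out after the first value was seen, which moved the epithelial-like median from -0.1765 to -0.2138 across the bound of -0.2, and the lengths are medians of annotated isoforms.

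Single genes with opposite directions are given as log2(OFF/ON), epithelial-like first. Emp3, a membrane protein gene, had -0.68 and 0.70. Grem1 had 0.78 and -0.53, with 23 and 55 UMIs in epithelial-like cells, a level near free RNA. Ifit1 had -0.76 and 1.97, and Rsad2 -1.05 and 3.90. Il33 had -4.69 and 1.33. Ly6a had -1.70 and 0.82. Barcodes 1 base apart numbered 61 pairs in Ptger4-ON and 17 in Ptger4-OFF, against 0.884 and 2.74 expected by chance, and the lesser barcodes held 1.41% and 0.473% of UMIs.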

How the results depend on the processing

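The values without barcodes over 50000 UMIs, without mixed cells, without lesser barcodes of pairs and inside 1 cluster were chosen after the data were seen. Both epithelial-like shares stayed within their intervals under every alternative run, at 65.1% to 67.9% in Ptger4-ON and 75.1% to 77.5% in Ptger4-OFF. Of the alternative values of list medians, 539 of the epithelial-like and 563 of the fibroblast-like stayed within their counting intervals, 59 and 16 moved beyond them, and 6 and 2 had the opposite sign, counted where the main interval left out 0. For named genes these counts were 2184, 97 and 1 in epithelial-like and 1993, 20 and 3 in fibroblast-like cells. These counts pool all alternatives, most of which moved few genes. With each cell weighted equally, 55 of 163 epithelial-like genes moved, 1 had the opposite sign and 107 stayed. Without barcodes over 50000 UMIs, 20 of the 163 moved. In fibroblast-like cells, equal weights moved 19 of 144 genes and gave 3 the opposite sign. The interferon median in fibroblast-like cells stayed between 0.52 and 0.68 and the cholesterol median, where it had a value, between 0.30 and 0.48. The cholesterol list had no value with members higher in the other class left out, since 0 of its 19 members remained. How much free epithelial RNA adds to the cholesterol list was not tested. Of the fibroblast-like clusters, only the larger was among the alternatives. Inside the smaller cluster the interferon median was 0.79 (interval 0.46 to 0.89) and the cholesterol median 0.96 (interval 0.38 to 1.30). The values below are median log2(OFF/ON) of lists, or log2(OFF/ON) of single genes, and the cause was not tested. Moved values are given for lists of the class itself, pathways and RNA quality with 5 measured members or more in the main values, and the other lists and single genes that moved are in these counts only.

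With TMM scaling, the epithelial-like values that moved included Paneth -1.42, ribosomal -0.20, mitochondrially encoded 0.66, oxidative phosphorylation 0.29, glycolysis 0.35 and tight junction -0.38. With median-of-ratios scaling, the epithelial-like values that moved included Paneth -1.41, cAMP/CREB 0.0580, cell cycle G2/M 0.0707, ribosomal -0.18, mitochondrially encoded 0.68, oxidative phosphorylation 0.30, glycolysis 0.36, unfolded protein 0.23 and tight junction -0.37. With 10 UMIs per gene, the epithelial-like values that moved included enteroendocrine 2.64. With 50 UMIs per gene, the epithelial-like values that moved included enteroendocrine 2.64. With at most 10% mitochondrial UMIs, the epithelial-like values that moved included mitochondrially encoded 0.59.

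With each cell weighted equally, the epithelial-like values that moved included enteroendocrine 2.69, fetal-like -1.53, ribosomal -0.18 and mitochondrially encoded 0.50. The epithelial-like values of opposite sign were dissociation and heat-shock stress 0.0207 and Csf1 0.22. The fibroblast-like values that moved included mitochondrially encoded -0.17, cholesterol 0.30 and unfolded protein 0.26. The fibroblast-like values of opposite sign were cell cycle G2/M 0.04796, Prap1 -0.25, Defa24 -0.0454 and Cdc20 0.0324.

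With members higher in the other class left out, the epithelial-like values that moved included enteroendocrine 2.64, YAP/TEAD -0.41, cAMP/CREB 0.13, glycolysis 0.59, unfolded protein 0.0235 (4 members left) and interferon response -0.0587. The epithelial-like value of opposite sign was dissociation and heat-shock stress 0.02505. The fibroblast-like values that moved included G1/S -0.23 and mitochondrially encoded -0.78, each of 1 gene left, and dissociation and heat-shock stress -0.26. The fibroblast-like value of opposite sign was oxidative phosphorylation -0.20, of 1 gene left. Without barcodes over 50000 UMIs, the epithelial-like values that moved included enterocyte 1.29, enteroendocrine 1.66, G1/S 0.16, cell cycle G2/M 0.13 and mitochondrially encoded 0.57. Inside one cluster of the class, the epithelial-like values that moved included enterocyte 0.43, goblet -0.16, fetal-like -0.81, YAP/TEAD -0.17, Notch -0.11, cell cycle G2/M 0.12, ribosomal -0.27, mitochondrially encoded 0.37, oxidative phosphorylation 0.11, lipid/PPAR 0.38, unfolded protein 0.23 and tight junction -0.33. The epithelial-like values of opposite sign were stem cell -0.21, Paneth 0.0858, glycolysis -0.0201 and interferon response 0.23. The fibroblast-like values that moved included cell cycle G2/M -0.0795, NF-kB 0.0583 and chemokine 0.21.

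Thinning to 500 UMIs or not thinning moved 53 epithelial-like and 18 fibroblast-like shares of cells with a UMI, which depth sets by construction, and left 19 and 6 within their intervals. With members higher in the other class left out, 3 epithelial-like and 8 fibroblast-like lists had no value, the fibroblast-like cholesterol list among them. Inside one cluster 1 epithelial-like list had none. No paired analysis was possible because each condition had 1 pooled library. Counting error, cell number and the absence of replicates limit all values, and few cells carry the enteroendocrine and tuft lists. Scaling factors shifted the median of all genes by at most 0.05.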

Other observations

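Lists of the other class were also counted. In epithelial-like cells, contractile genes were lower in Ptger4-OFF for all 10 measured members (median -0.69 (interval -1.06 to -0.48)), such as the actin-binding genes Flna (52.6 and 17.2 CPM), Cnn2 (119.6 and 56.7 CPM) and Actn1 (258 and 126 CPM). The stromal chemokine list had a median of -0.62, the protease list -0.51 (Plaur, the urokinase receptor gene, 27.3 and 8.81 CPM), the matrix list 0.01 (Thbs1 63.4 and 22.8 CPM; Col4a1 8.13 and 1.32 CPM; -0.97 inside the cluster led by Clu, 0.32 in the cycling cluster, -0.58 in that led by Nrn1) and the niche signal list 0.12. Areg, an EGF receptor ligand gene, was mostly epithelial, at 1026 and 626 CPM, and Ereg had 28.6 and 14.7 CPM. Among the keratins used as epithelial markers, Krt8, Krt18 and Krt19 were 1.70-fold, 1.61-fold and 1.65-fold higher in Ptger4-ON, and the epithelial marker list had a median of -0.31, but 0.20 inside the cluster led by Clu. In fibroblast-like cells the fibroblast marker list had a median of -0.08, with Thy1 at 39.8 and 75.6 CPM and Vim at 1679 and 2074 CPM, and the enterocyte genes seen there (Fabp1 3.42 and 24.5 CPM) had a median of 1.02, at levels near free RNA. The fibroblast marker list had a median of 0.06 in epithelial-like cells. In fibroblast-like cells the epithelial marker list had 0.60, crypt stem cell 0.13, Paneth -0.12, goblet -0.55 (3 measured members), enteroendocrine -0.24 (2), tuft 0.16 (3), tight junction and keratin 0.10 and MHC class II -0.23 (2). At least 5 of 1000 thinned UMIs of the fetal-like list were seen in 55.3% and 23.1% of epithelial-like and in 84.6% and 88.2% of fibroblast-like cells, and of the enterocyte list in 14.7% and 21.8% of epithelial-like cells. Many cells lay close to this limit of 5, with 3 to 6 UMIs of the enterocyte list in 84 and 251 epithelial-like cells, of the fetal-like list in 156 and 340, of the Paneth list in 63 and 78 and of the goblet list in 28 and 32, so these shares depend on it.

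The following values were chosen after they were seen and are given without an explanation. The chromosome Y genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 1 and 1 UMIs in epithelial-like cells (Ptger4-ON, Ptger4-OFF) and to 60 and 53 UMIs in fibroblast-like cells, which is 34.15 CPM [26.1 to 43.96] and 28.8 CPM [21.6 to 37.7]. Xist, expressed from the inactive X chromosome of female cells, had 667 and 873 CPM in epithelial-like and 372 and 347 CPM in fibroblast-like cells. Of 288 and 360 fibroblast-like cells, 172 and 222 had an Xist UMI, 21 and 22 had a chromosome Y UMI, and 2 and 0 had both. The mitochondrial gene mt-Nd3 had 0 UMIs in epithelial-like cells of both libraries, which allows up to 3 UMIs, and 87 and 53 UMIs in fibroblast-like cells, spread over 60 and 48 cells. No genome sequence was at hand to test how reads were placed for mt-Nd3.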
